A study of Mus musculus with 15 samples.

How the data were processed

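The data were peak lists of open chromatin from ATAC-seq of P14 CD8+ T cells, 1 list for each of 6 tissues, from 15 libraries. Per the labels, cells from 10 to 15 mice were pooled for each library and 20000 cells were sorted. Per the labels' protocols, tissues other than spleen were sorted for cells not marked by the injected antibody, the intestinal cells were released without collagenase, and kidney, salivary gland, fat and liver were minced and treated with collagenase. Blood is named in the description of the study and was not analysed here.

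Each deposited list had the columns of a narrowPeak file, with several summits for some intervals. The authors had combined the libraries of a tissue, since the deposited lists hold no value per library. Aligner, peak caller, versions, filters, read shifting and genome build are not given in the sources used here. The deposited score ran from 540 to 1000, and 540 is the scaled score of an irreproducible discovery rate of 0.05, so the lists look filtered at that rate across libraries. The deposited signal value is the peak caller's height of a summit, and it was used only to rank and describe regions within a list. The deposited −log10 p-values and −log10 q-values were used only to shorten lists in alternatives; between 1.02% and 1.29% of summits had a q above 0.05. The deposited summit offset, the other value used, places the summit in its interval; 1 fat row without a summit was given the middle of its interval. Depth per library is unknown, and the number of libraries, which differs between tissues, limits the precision of the shorter lists. No row was left out and 0 columns of other samples were present.

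Intervals on chromosomes 1 to 19, X and Y were merged across lists where they overlapped by at least 1 bp, and a union region was called in a tissue when an interval of its list overlapped it. Classes were regions called in all 6 lists, in 1 list alone (private) and in all lists but 1. Pairs of lists were compared by the Jaccard index. Shares have Wilson 95% intervals that cover counting error only. Groups were taken from the tissue label of each library.

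Gene names came from a table of RefSeq genes of assembly GRCm38.p6, which was used for names and neighbourhood only. To check that positions match, gene ends were set against spleen summits: 21.2% of 43774 gene ends had a summit within 100 bp, against 4.66% with the ends moved by 1000 bp and 2.41% by 5000 bp. The table gives neither strand nor exons, so the planned nearest start site became the nearest protein-coding gene within 100 kb, the planned promoter became 1 kb around either gene end, and exons and introns were not separated. Motif shares were planned and not run, because no genome sequence was used here. A region inside overlapping genes went to the gene whose end was nearer, so such links are uncertain.

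Gene lists (15 of T cell programmes and 12 of other cell types), the rule for named genes, the classes and most settings to be varied were fixed before the data were examined; equal numbers of intervals and the 50% cover were added afterwards. For each list and class, the share of the list's regions in the class was set against 10000 random lists of the same size matched on regions per gene in 10 bins (seed 20), and its percentile is a description of these lists, not a test of tissues. A list is said to stand apart outside the central 95%. For each tissue, the share of a list's spleen regions kept and the share of its regions not called in spleen were added after the lists were seen, as were regions called in exactly 2 lists. Named genes were, by that rule, the 10 with the most resident-shared regions, the 10 with the most spleen-private regions, the 5 with the most private regions in each other tissue, up to 4 members per list with the largest difference between resident-shared and spleen-private counts, and a set of genes always given. Some of the genes and regions this rule selects were not used here. Named regions came from the 3 private regions of highest signal in each list and the 3 resident-shared regions with the highest minimum rank. Of 36 residency genes 35 were matched, and all 35 recirculation genes.

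The functions were tested on simulated data. Among 3000 simulated regions in 6 lists every class count was recovered (100%). The gene list comparison was run on 14660 genes with lists of 35 genes, at the overall share of the spleen-private class (7.25%). The upper limit was passed by 1% of 200 unchanged lists, by 30% of 100 lists with a 1.5 times higher share and by 72% of 100 lists with a 2 times higher share. So a list inside the limits may still differ. Many lists were raised together among the genes that random lists were drawn from, so the rates may be too low for these ratios. Classes with smaller shares were not simulated. Alternatives were equal numbers of summits (120632) or of intervals (46387), a minimum −log10 q of 5, 200 bp windows around summits, intervals covering 50% of the region, autosomes only, each list left out, a gene distance of 20 kb, gene bodies with 50 kb on either side, and unmatched lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.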

Results

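Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in P14 CD8+ T cells taken from 6 mouse tissues 32 days after infection with the Armstrong strain of lymphocytic choriomeningitis virus (LCMV). P14 cells carry a transgenic T cell receptor for a peptide of this virus, so cells of the same specificity were compared across tissues. The 15 libraries came from spleen (4), the intraepithelial lymphocytes (IEL) of the small intestine (3), kidney (2), salivary gland (2), gonadal fat (2) and liver (2). Each library started from 20000 sorted cells pooled from 10 to 15 mice. In the tissues other than spleen, an antibody injected 3 minutes before death marked cells inside blood vessels, and unmarked cells were sorted. The comparisons ask how open chromatin of memory cells within tissues differs from that of spleen memory cells and from tissue to tissue.

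The deposited data were 1 peak list per tissue, so a difference between tissues has no replicate check here, no p-value is given, and intervals cover counting error only. Read depth was not stated and is unknown. The spleen list held 153447 summits in 55553 intervals and covered 30.6 Mb. The IEL list held 135003 summits in 56077 intervals (27.3 Mb). The lists of the tissues with 2 libraries were shorter, with 120632 summits in salivary gland, 121020 in fat, 124830 in kidney and 129520 in liver. By summits and covered length, though not by intervals, the order of spleen, IEL and the other lists followed the number of libraries. Merging the intervals of all lists gave 67286 union regions with a median width of 468 bp, of which 64515 (95.9%) were linked to 14660 protein-coding genes.

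Markers of most other cell types had regions at gene ends in like numbers in every list. T cell identity genes such as Cd3e and Cd8a had a region at a gene end for 19 or 20 of 20 genes in every list, and housekeeping genes for 19 of 20. Hepatocyte markers were at 4 of 18 and adipocyte markers at 8 of 16 in all 6 lists, the liver and fat lists included. Intestinal epithelial markers were at 3 of 20 in IEL, where Epcam, Elf3 and Cldn7 had a region, against 4 to 6 in the other lists. Kidney tubule markers were at 3 of 16 in kidney and 4 in spleen, salivary epithelial markers at 2 of 17 in salivary gland and 1 in spleen, and fibroblast markers at 2 of 16 throughout. Endothelial markers were at 1 or 2 of 16, macrophage and monocyte markers at 7 or 8 of 18, neutrophil and mast cell markers at 0 or 1 of 14, and CD4 T cell markers at 7 or 8 of 12. B cell markers varied more, from 5 of 15 in fat to 8 in spleen and in IEL, as did gamma-delta T cell and innate lymphoid markers, from 2 of 13 in kidney to 6 in spleen, fat and liver.

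Much of the accessible chromatin was shared, and spleen and IEL had the most regions of their own. In all 6 lists 33265 regions (49.4% of the catalogue) were called, and 30.5% of these lay within 1 kb of a gene end (Wilson 95% interval 30.0 to 31.0). Regions called in 1 list alone numbered 12591. Spleen had 4956 such private regions, 9.20% of its list, and IEL had 4287, 8.30% of its list. Liver had 1101 (2.34%), salivary gland 968 (2.14%), fat 742 (1.69%) and kidney 537 (1.19%). Private regions lay near gene ends less often, with 10.5% in spleen (9.65 to 11.4) and 8.93% in IEL (8.12 to 9.82). With the same number of intervals taken from every list, spleen had 2374 private regions, IEL 2237 and fat 1432, and with the same number of summits 4569, 4207 and 751, so these counts depend on how list length is made equal.

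**Figure D1:**
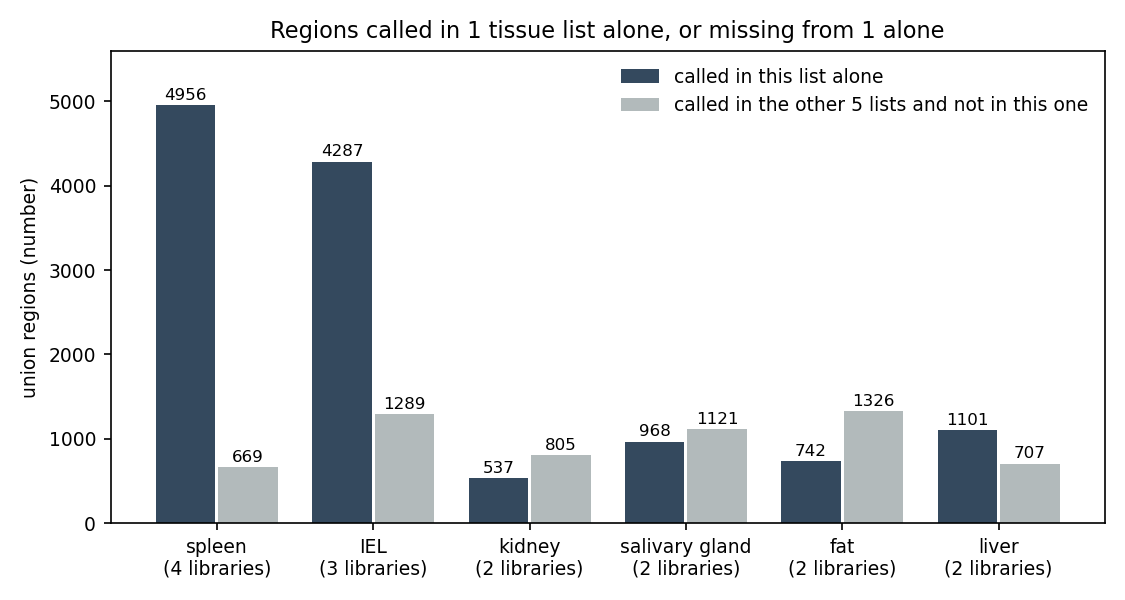
Number of union regions called in a tissue list alone (dark bars) and called in the other 5 lists but not in that list (light bars), by tissue, with the number of libraries behind each list. Spleen (4956) and IEL (4287) have the most private regions, and the lists from 2 libraries have 537 to 1101.

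Spleen was compared with the tissues to find chromatin that distinguishes recirculating from resident memory cells. Genes of recirculation and lymphoid homing kept fewer spleen regions than matched lists in every tissue but liver. Totals below those of spleen were common in other lists too: 25 of 35 recirculation genes in IEL and 29 in kidney had fewer regions than in spleen, against 10 and 19 of 20 T cell identity genes. Klf2, the transcription factor that drives expression of the egress receptor gene S1pr1, had 9 regions in spleen, 6 in liver, 5 in IEL and kidney, and 4 in salivary gland and fat. S1pr1 itself had 25 in spleen and 16 to 20 in the tissues. Itgb1, the beta-1 integrin gene, had 22 in spleen, 14 in kidney and in salivary gland, 12 in liver, 7 in fat and 6 in IEL.

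Of the 474 regions linked to the 35 recirculation genes, 70 (14.8%, Wilson 95% interval 11.9 to 18.2) were called in spleen alone. The median of 10000 random gene lists matched on regions per gene was 8.22%, and the observed share was higher than in 99.99% of them. Ripor2 had 9 such regions, Zeb2, a repressor active in terminal effector cells, had 8, Itgb1 had 7 and S1pr1 had 4. Foxp1, a regulator of T cell quiescence, had the most spleen-private regions of any gene (12 of its 83 regions), followed by Nrp1, Arhgef3 and Ripor2 with 9 each. Prkce, Zmiz1 and Zeb2 had 8 each, and Immp2l, Sgk1 and Irf2 had 7 each. The spleen-private regions with the highest signal value lay inside Aspm (chromosome 1, 139481024 to 139481440, signal 26.4), inside Pias2 (chromosome 18, 77140129 to 77140542, signal 25.6) and inside Fnip2 (chromosome 3, 79504413 to 79504870, signal 25.5).

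The share of spleen regions of recirculation genes that was also called in a tissue was 63.0% in IEL (58.2 to 67.6), 64.0% in salivary gland (59.2 to 68.6), 64.3% in fat (59.5 to 68.8), 67.5% in kidney (62.8 to 71.9) and 74.2% in liver (69.7 to 78.2). Over all linked spleen regions the share was 80.2% in IEL, 75.7% in salivary gland, 77.9% in kidney and 79.3% in liver. The recirculation genes stood at percentile 0.45 or lower of matched lists in IEL, kidney, salivary gland and fat, and at percentile 13.65 in liver. B cell markers, with 28 spleen regions, also kept few, at percentiles 0.08 in fat, 0.665 in kidney, 1.265 in salivary gland, 3.195 in liver and 3.255 in IEL. For recirculation genes, liver exceeded the mean of the other 4 tissues by 9.49 percentage points (matched median 3.00), more than in 99.97% of matched lists. The same difference for naive and central memory genes, which share Ccr7 and Lef1 among others with the recirculation list, was 10.8 points (matched median 2.90), higher than in 99.98% of lists. Ccr7, the receptor for lymph node chemokines, had 22 regions in spleen, 21 in liver (20 of them shared with spleen) and 13 to 17 in the others. Bach2, a repressor that keeps T cells in a memory or naive state, had 51 in spleen and in liver, 42 in fat and 30 to 34 in IEL, kidney and salivary gland. Of its 51 spleen regions, 44 were kept in liver, 38 in fat and 30 to 32 in the other tissues, and 7 liver regions were not called in spleen. These comparisons of kept regions were chosen after the lists were seen, and all 5 share the spleen list, so part of their likeness may come from it.

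**Figure D2:**
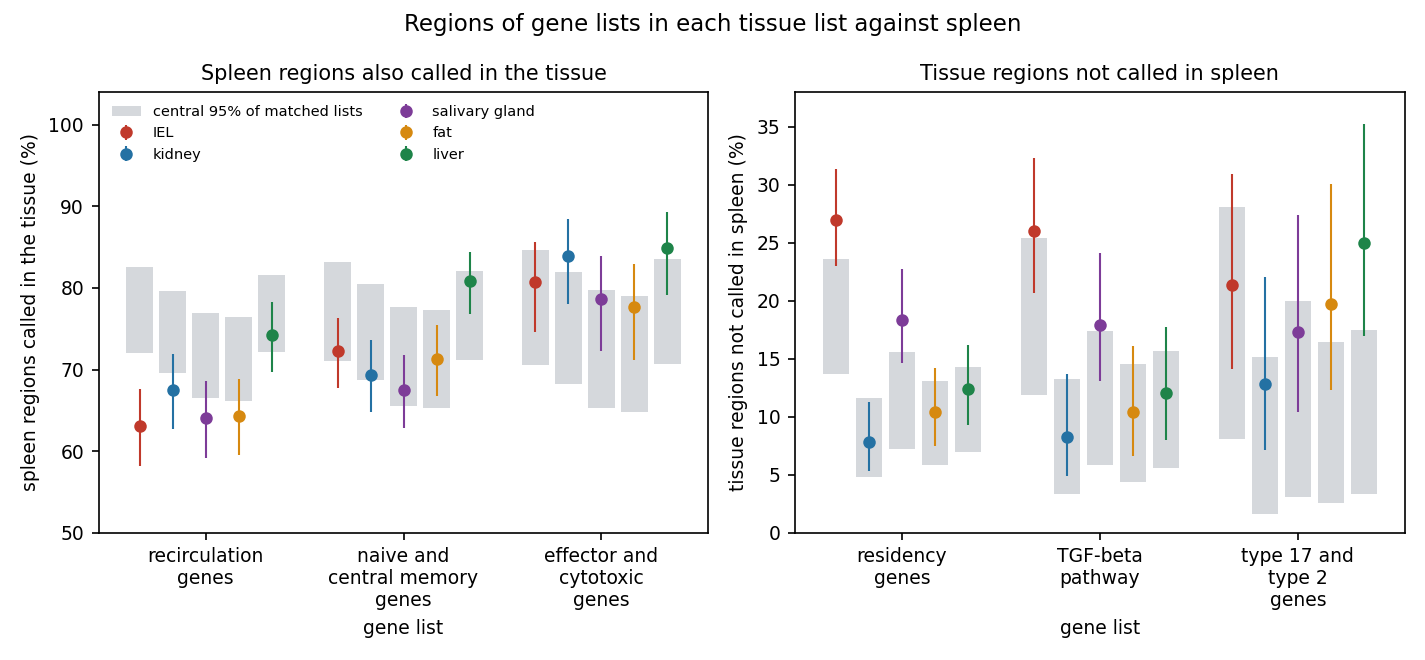
Share of the spleen regions of 3 gene lists also called in each tissue (left, percent) and share of each tissue's regions of 3 gene lists not called in spleen (right, percent). Points are observed shares with Wilson 95% intervals and grey spans hold the central 95% of matched random lists; recirculation genes lie below the span in every tissue but liver.

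Effector, gut homing and chemokine receptor genes also differed from matched lists in some tissues. Effector and cytotoxic genes, which include Ifng, Gzmb and Prf1, kept 83.9% of spleen regions in kidney (percentile 99.42) and 84.9% in liver (percentile 99.05). With equal numbers of intervals these fell to percentiles 94.98 and 90.97, inside the central 95% of matched lists. Retinoic acid and gut homing genes kept 61.8% in IEL and 60.5% in kidney, at percentiles 0.24 and 0.215 (matched medians 78.8% and 75.9%). Rxra, a retinoid receptor, had 11 regions in spleen and 3 in IEL. Chemokine receptor genes kept 64.6% in IEL (percentile 0.24). They include Ccr7 and Cx3cr1 of the recirculation list, which kept 13 of 22 and 3 of 9 there, so the 2 results are not independent. T cell identity genes kept 67.2% in kidney (percentile 1.14, and 2.72 with 200 bp windows, inside the central 95%), and natural killer receptor genes 63.1% in salivary gland (percentile 1.825). Lipid genes kept 83.1% in salivary gland and 82.0% in fat (percentiles 98.16 and 97.745), and with equal numbers of intervals 86.65 and 88.965, inside the central 95%.

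Regions missing only from spleen, called in all 5 tissues, formed the resident-shared class and numbered 669. No class of this kind was smaller: 707 regions were missing only from liver, 805 from kidney, 1121 from salivary gland, 1289 from IEL and 1326 from fat. They lay near a gene end in 9.57% of cases (7.56 to 12.0). Inpp4b, a phosphatase gene of the residency list, had 3, as did Hivep3, Rgs9, Nedd9 and Atxn1. Bcl2l15, Hspb7, Ptpn3, Ergic1 and Lama3 had 2 each. The regions whose lowest rank over the 5 lists was highest lay between genes nearest Ptpn5 (chromosome 7, 47139705 to 47140476), between genes nearest Ptpn11 (chromosome 5, 121087730 to 121088559) and inside Fyb (chromosome 15, 6540016 to 6540640). Of 547 regions of residency genes, 11 (2.01%) belonged to this class, higher than in 94.18% of matched lists, which does not set the list apart. Alternatives fell on either side of the limit: 98.33 with equal numbers of intervals, 99.85 with 200 bp windows, and 71.86 when 4 of the 5 tissues were enough, where the class held 1566 regions.

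Itgae and Cd69, the integrin and the egress antagonist used as residency markers, had no more regions in any tissue than in spleen. Itgae, with 10 regions, had 8 in spleen and in IEL, 7 in kidney, salivary gland and liver, and 5 in fat. Of these, 2 in IEL and 1 in salivary gland were not called in spleen. Cd69, with 25, had 18 in spleen, 17 in IEL and 13 to 16 in the others, and 2 or 3 in each tissue but liver were not called in spleen. Tbx21, the gene of the effector factor T-bet, had 11 in spleen and in fat and 10 in the others. Tcf7, a stem-like memory factor gene, had 18 in spleen and in IEL and 15 to 19 elsewhere. Eomes, a T-box factor gene, had 17 in spleen and 10 in IEL, and Klrg1, a terminal effector marker, had 12 in spleen, IEL and liver and 8 in salivary gland. Cxcr6 had a region in liver alone, which may belong to a neighbouring gene that overlaps it.

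**Figure D3:**
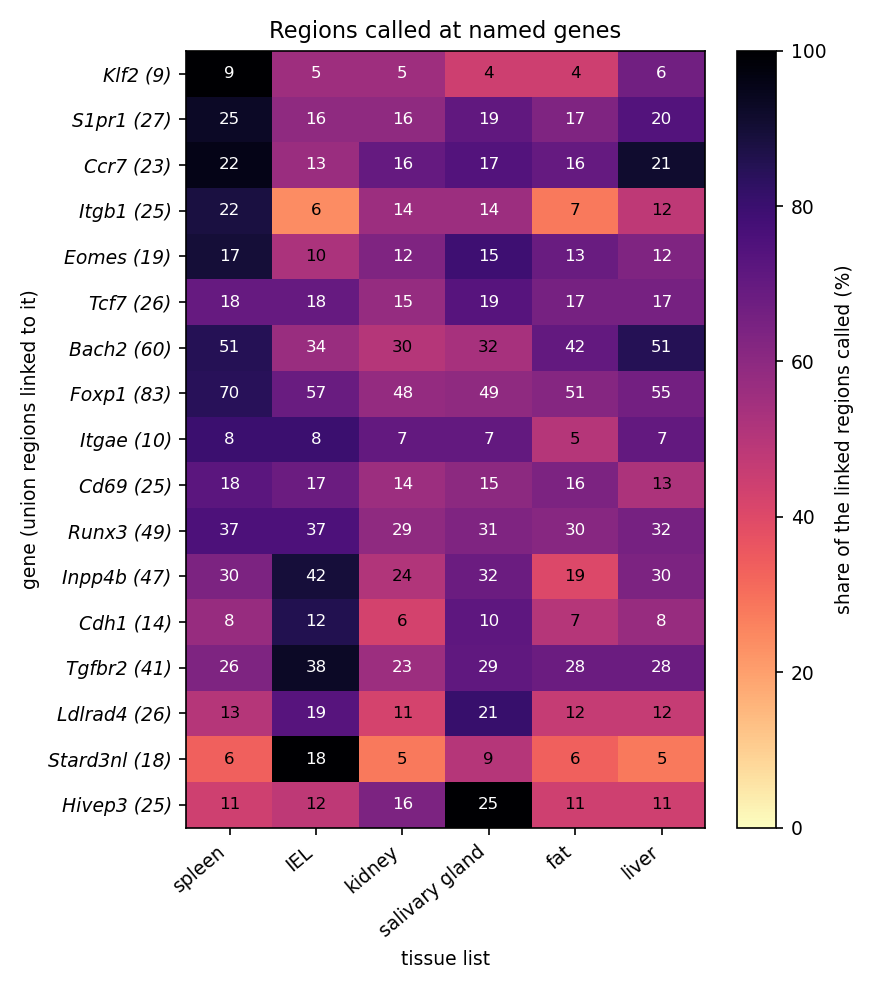
Number of regions called per tissue list (figures in the cells) and their share of the union regions linked to the gene (colour, percent), for 17 named genes. Klf2, S1pr1 and Itgb1 have most regions in spleen, Tgfbr2, Inpp4b and Stard3nl in IEL, and Hivep3 in salivary gland.

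IEL cells gained regions at residency and TGF-beta pathway genes. Of the IEL regions of residency genes, 27.0% (23.0 to 31.3) were not called in spleen, against a matched median of 18.5%, higher than in 99.97% of lists. For TGF-beta pathway genes the share was 26.0% (20.6 to 32.3), higher than in 98.25%. Its excess over the other tissues was 13.9 points (matched median 7.79, percentile 98.53, and 97.17 with 200 bp windows). Tgfbr2, the type II TGF-beta receptor gene, had 38 regions in IEL, 26 in spleen and 7 called in IEL alone. Runx3, a factor required for tissue residency of CD8+ T cells, had 7 IEL-private regions and 5 spleen-private, with 37 regions in each list. Cdh1, the gene of E-cadherin, had 12 regions in IEL against 8 in spleen. Markers of endothelium (9 of 28 regions, percentile 98.15) and of neutrophils and mast cells (4 of 10, percentile 99.08) stood apart in IEL as well, but not in every alternative (lowest percentiles 95.955 and 88.48). Among genes chosen after their values were seen, Itga1, the gene of the collagen-binding integrin CD49a, had 20 regions in IEL against 13 in spleen, and Litaf had 17 against 6.

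The IEL gain at residency genes exceeded the mean of the other 4 tissues by 14.7 percentage points, more than in 99.98% of matched lists. The matched median was already 7.96 points. With equal numbers of intervals the difference was 9.93 points (matched median 3.58, percentile 99.94). Private regions are part of the regions not called in spleen, so they are not an independent check. Of 547 regions of residency genes, 57 (10.4%, 8.13 to 13.3) were called in IEL alone, higher than in 99.30% of matched lists but in 95.87% of unmatched ones. Recirculation genes had 9 of 474 (1.90%) and stood at percentile 0.01. Effector and cytotoxic genes stood at percentile 1.33 and chemokine receptor genes at 2.335. These were 12.5 with gene bodies and 50 kb on either side and 12.28 with 200 bp windows around summits, inside the central 95%. Few IEL regions were new at immediate early genes (9.88%, percentile 0.495) and natural killer receptor genes (5.88%, percentile 0.635), and with equal numbers of intervals these stood at 5.635 and 7.485. At natural killer receptor genes few were new in salivary gland and fat too (percentiles 1.18 and 2.285, and 2.965 and 3.03 with equal numbers of intervals). By number of IEL-private regions, Maml2 (9) came first, then Stard3nl and Pdzd2 (8), and Tgfbr2 and Dapk2 (7). Of the 18 regions linked to Stard3nl, 6 overlap Tcrg, the T cell receptor gamma locus beside it, so the link to Stard3nl is uncertain. Ccr9, the gut homing receptor gene, had 7 regions in IEL, 6 in spleen and 2 in kidney, and Hic1, a retinoic acid induced repressor gene, had 4 in IEL and 3 in spleen. The IEL-private regions of highest signal lay near 1700019A02Rik (chromosome 1, 53149933 to 53150383, signal 28.2), near Cdc25a (chromosome 9, 109902684 to 109903181, signal 26.8) and inside Ube3c (chromosome 5, 29664665 to 29665130, signal 25.8). Epithelial markers, as given above, were at gene ends in IEL for 3 of 20 genes.

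**Figure D4:**
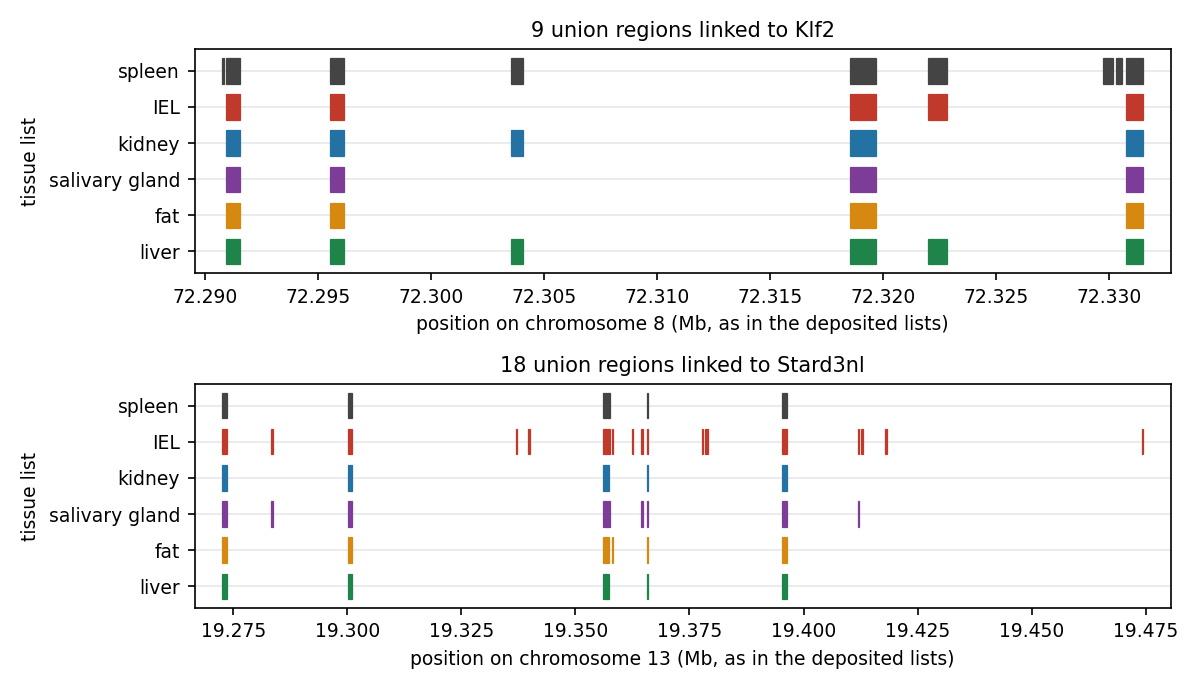
Union regions linked to Klf2 (upper panel, 9 regions) and Stard3nl (lower panel, 18 regions, chromosome 13), drawn at their positions in Mb as in the deposited lists, with a row of blocks for each tissue list that called them. Klf2 has 5 regions in IEL against 9 in spleen, and Stard3nl, beside the T cell receptor gamma locus, has 18 in IEL against 6 in spleen.

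Salivary gland cells shared this gain. Of their regions of residency genes, 18.4% (14.7 to 22.7) were not called in spleen, against a matched median of 11.1%, higher than in 99.83% of matched lists, and of their regions of TGF-beta pathway genes 17.9% (13.1 to 24.1), higher than in 98.20%. The residency share exceeded the mean of kidney, fat and liver by 8.18 points (matched median 1.58), more than in 99.98% of lists. In kidney, fat and liver the residency shares were 7.81%, 10.4% and 12.4%, inside the central 95% of matched lists, though with 200 bp windows liver stood above it (percentile 99.16). Ldlrad4, an inhibitor of TGF-beta signalling, had 21 regions in salivary gland, 19 in IEL and 13 in spleen. Hivep3 had 25 in salivary gland, of which 6 were private, against 11 in spleen, and Dock9 had 4 private regions, Lama3 and Zfp644 3 each. The salivary-private regions of highest signal lay nearest Dhrs2 (chromosome 14, 55337956 to 55338377, signal 21.5), with no gene linked (chromosome 15, 52966387 to 52967183, signal 20.1), and nearest Tcf7l2 (chromosome 19, 55697604 to 55698109, signal 19.4).

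Liver cells stood out at type 17 and type 2 genes. Of the liver regions of these genes, 25.0% were not called in spleen (matched median 9.64%), higher than in 99.99% of matched lists, and 9 of 125 (7.20%) were private to liver, higher than in 99.97%. Of the 18 genes, 3 had more regions in liver than in spleen, 5 fewer and 10 as many. Gata3, the type 2 lineage factor gene, had 3 liver-private regions but 13 regions in liver and in spleen, Rora had 24 in liver against 27, and Il23r, the receptor gene of a type 17 cytokine, had 10 regions in liver against 6 in spleen (chosen after its values were seen). In fat the share not called in spleen was 19.7% (12.3 to 30.0), higher than in 99.67% of lists. With equal numbers of intervals these values fell to percentiles 97.205 for the liver gain, 82.93 for the private share and 91.74 in fat, all inside the central 95%. The liver excess over the other tissues, 7.19 points, went from percentile 99.55 to 86.37. Gamma-delta T cell and innate lymphoid markers, which include Il23r, also had liver regions not called in spleen (21.3%, percentile 99.085), as did neutrophil and mast cell markers (3 of 9 regions, percentile 98.675, and 92.695 with equal numbers of intervals). Bcl2, the survival gene, and Bach2 led the liver-private counts with 4 each, then Spef2, Map3k5 and Asap1 with 3. Bcl2 also had 3 private to IEL and 3 to salivary gland, with 25 regions in liver and in IEL. Bach2 had 4 private to spleen, and Asap1 had 4 private to IEL. The liver-private regions of highest signal lay nearest Gm4832 (chromosome 17, 88176263 to 88176575, signal 17.4), nearest Ppp1r14c (chromosome 10, 3334549 to 3335025, signal 16.3) and inside Fchsd2 (chromosome 7, 101213866 to 101214125, signal 16.0).

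Fat and kidney had the fewest private regions, but with equal numbers of intervals fat had 1432, more than salivary gland (1293) and liver (874). The fat list has the fewest intervals and was not cut there, so its rise came from intervals removed from the other lists. In fat, Lef1, a partner of Tcf7 in naive and memory T cells, had 4 private regions, Gipc2 3, and Myo16, Zfp523 and Rgs9 2 each. Lef1 also had 4 regions private to IEL, and fewer regions in fat (22) than in spleen and IEL (24 each). Naive and central memory genes had 13 of 517 regions (2.51%) private to fat, higher than in 98.52% of lists, and at percentile 87.79 with equal numbers of intervals. The fat-private regions of highest signal lay nearest Hbs1l (chromosome 10, 21287180 to 21287752, signal 17.8) and inside Myo16 (chromosome 8, 10565622 to 10566271, signal 15.2). Kidney tubule markers had 5 of 22 kidney regions not called in spleen (percentile 98.51, and 91.68 with equal numbers of intervals). In kidney, Vav3 and Atxn1 had 3 private regions each, and Rbm24, Lrrn4 and Asns 2 each. Atxn1, with 74 regions, had more private to IEL (7) and to spleen (5). The kidney-private regions of highest signal lay inside Gsn (chromosome 2, 35270752 to 35270904, signal 16.8), at an end of Lrat, a retinoid storage enzyme gene (chromosome 3, 82903704 to 82904230, signal 15.4), and with no gene linked (chromosome 8, 34550763 to 34551061, signal 13.9).

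Over the 15 programme lists and 7 classes (the private classes and the resident-shared class), 4 of 105 comparisons lay above the central 95% of matched lists and 3 below, where 2.62 are expected on each side by chance. TGF-beta pathway, retinoic acid and gut homing, natural killer receptor, inhibitory receptor, lipid, interferon response, immediate early, housekeeping and T cell identity genes lay inside in all 7 classes. Among the 84 comparisons of cell type lists, 2 lay above and 1 below: adipocyte markers in liver alone (3 of 28 regions, percentile 99.645), CD4 T cell markers in the resident-shared class (4 of 95, percentile 98.885), and macrophage markers in IEL alone (0 of 73, percentile 0.425). Each fell inside the central 95% in at least 1 alternative. Of 75 comparisons of kept regions, 4 lay above and 9 below, and of 75 of regions not called in spleen, 6 above and 7 below, where 1.88 are expected on each side. Few regions were new at naive and central memory genes in kidney (3.65%, percentile 0.83, and 0.61 to 2.32 in the alternatives) and at lipid genes in salivary gland (2.63%, percentile 0.725, and up to 3.725). For the 12 cell type lists, 0 of 60 comparisons of kept regions lay above and 5 below (B cell markers in 3 tissues, intestinal epithelial markers in IEL and fat), and 5 of 60 of regions not called in spleen lay above and 0 below, where 1.5 are expected on each side.

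Tissue lists were compared with each other for closeness. Fat and liver were the nearest pair by union regions (Jaccard index 0.787), followed by kidney and salivary gland (0.782). IEL was most distant from fat (0.685) and spleen (0.690), an order that turned with shared base pairs (0.6599 and 0.6589). Spleen was closest to liver and kidney (0.731 each). Pairs of lists from 2 libraries ran from 0.757 to 0.787, and pairs that include IEL or spleen from 0.685 to 0.731. Closeness therefore cannot be told apart from list length and number of libraries. Of the kidney regions 92.6% were also called in spleen (92.4 to 92.9), of fat 91.8%, of liver 90.7%, of salivary gland 89.9% and of IEL 83.4% (83.1 to 83.7). With equal numbers of intervals the liver share passed that of fat, as given below. In the other direction, 79.9% of spleen regions were called in IEL, 79.1% in liver, 77.6% in kidney, 75.3% in salivary gland and 74.6% in fat.

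**Figure D5:**
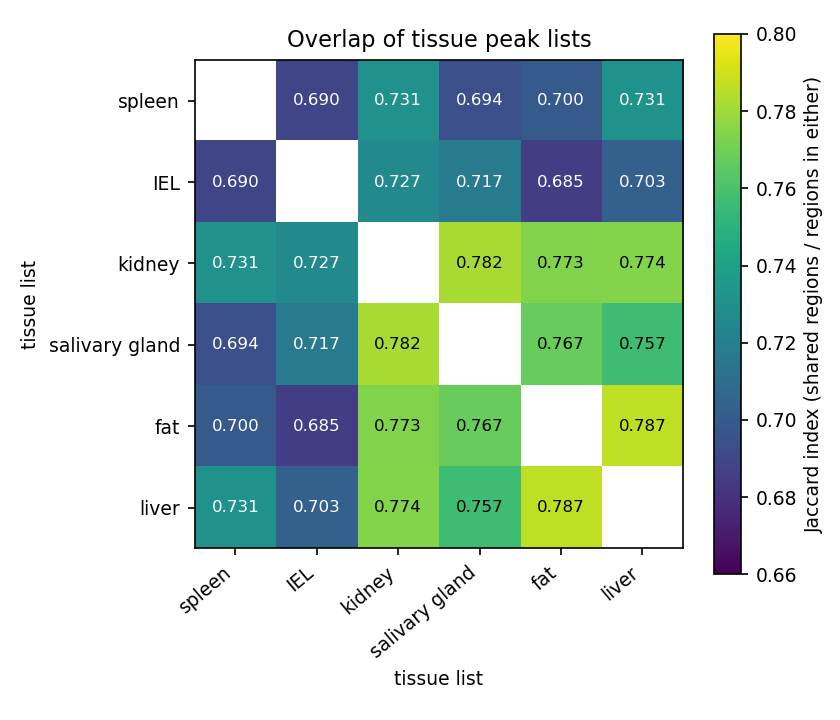
Jaccard index (regions called in both lists divided by regions called in either) for each pair of the 6 tissue lists. Values run from 0.685 for IEL and fat to 0.787 for fat and liver.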

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

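The comparisons of kept and gained regions, the equal-interval tests and the tests on B cell and epithelial markers were chosen after the results were seen. Over 37 quantities compared across the 5 tissue lists other than spleen, 2 had a tissue far from the others, and chance gives such a gap in about 1 of 20. The share of the list called in no other tissue was 8.30% in IEL against 1.19% to 2.34% in the others. Immediate early genes include Fos, Jun and Nr4a1. They kept 83.4% of their spleen regions in IEL, against 73.7% to 74.9% in kidney, salivary gland, fat and liver. Against matched lists the IEL share was inside the central 95% (percentile 90.695, median 78.7%, and 24.565 to 91.99 in the alternatives). Over all linked spleen regions, IEL also kept the largest share (80.2%). Per the labels, IEL was the only one of these tissues prepared without collagenase, but its list also came from more libraries (3 against 2). Whether any of these accounts for the gap was not tested.

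Regions called in spleen alone gathered at recirculation genes. A longer spleen list is argued against as the whole cause. With equal numbers of intervals recirculation genes stood at percentile 99.87, and the IEL list, also long, had few private regions there (percentile 0.01). The cut tests only the intervals it removed, since a length effect alike at all genes would leave percentiles among matched lists unchanged. B cells in the spleen sort could add regions at Klf2 or Ccr7, which B cells also use, although the sort for P14 cells would remove them: 10.8% of the regions of 15 B cell markers were called in spleen alone (4.29 to 24.7), and that interval holds the 14.8% of recirculation genes, so the markers are too few to decide. Cd79a and Cd79b had a region at a gene end in spleen and also in IEL, but B cell markers kept few of their 28 spleen regions in fat (14, percentile 0.08), kidney (0.665) and salivary gland (1.265), as recirculation genes did. A difference between recirculating and resident cells stays open and untested, and more libraries in spleen could still matter beyond list length.

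Regions called in IEL and not in spleen gathered at residency genes. A longer IEL list is argued against as the whole cause, since with equal numbers of intervals the residency genes stood at percentile 99.85. As for spleen, the cut tests only the intervals it removed, and depth and number of libraries were not made equal. Intestinal epithelial cells in the IEL sort stay open, although the sort for P14 cells would remove them. Of 20 epithelial markers, 3 had a region at a gene end in IEL (Wilson 95% upper bound 36.0%) against 4 to 6 in the other lists, and so few markers do not decide. Of the 20 markers, 4 are on another list as well. The gut environment, the way the tissue was prepared and other cells, such as endothelium, stay open and untested. Endothelial markers stood at percentile 98.15 in IEL but at 95.955 in an alternative, and the sort for P14 cells would remove such cells.

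Spleen regions of recirculation genes were kept in liver more often than in the other tissues. The longer liver list is argued against as the whole cause, since the difference stood at percentile 99.92 with equal numbers of intervals. The cut again tests only the intervals it removed, and depth was not made equal. Circulating cells in the liver sort, which the injected antibody should remove, cannot be told apart from a liver programme: among spleen regions called in no tissue but liver at most, those at recirculation genes were called in liver 1.37 times as often as others of like signal (0.880 to 2.04), an interval that includes equality. Circulating cells would also have made this share higher in liver than elsewhere, and it was 15.8% in liver, 5.93% to 8.27% in kidney, salivary gland and fat, but 23.1% in IEL. By the bound set beforehand, the IEL share would have argued against circulating cells; that bound was judged wrong after its value was seen, because the IEL list comes from 3 libraries and is longer, so the tissue itself also stays open, untested.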

How the results depend on the processing

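Equal intervals, 50% cover, and all settings for kept and gained regions were chosen after seeing the data. Of 213 values under alternatives, 177 stayed within their 95% interval or, for counts, within 1.5 times. This differed by setting: with equal numbers of intervals 21 moved and 15 stayed. With equal numbers of summits, and with a minimum −log10 q of 5, all 36 stayed. Equal intervals gave 2374 regions private to spleen, 2237 to IEL and 1432 to fat, and 524 missing only from kidney and 860 only from fat. Shares called in spleen were then 85.0% for IEL, 90.0% for kidney, 86.3% for salivary gland, 87.0% for fat and 88.9% for liver. Shares of gene list regions were 8.81% (recirculation, spleen alone), 3.67% (residency, missing only from spleen, percentile 98.33), 7.13% (residency, IEL alone), 0.952% (recirculation, IEL alone) and 2.75% (type 17 and type 2, liver alone). Recirculation genes kept 76.2% in kidney, 71.6% in salivary gland, 74.2% in fat and 80.6% in liver, TGF-beta genes gained 25.4% in salivary gland, and effector genes kept 88.5% in kidney. Equal intervals shorten the longest lists most. The fat list, with 46387 intervals, was not cut, so its rise from 742 to 1432 private regions came from intervals removed from the other lists. Whether shortening accounts for each of the other shifts was not tested. Windows of 200 bp gave 8475 regions private to spleen, 835 to kidney and 1151 to fat, 2148 missing only from IEL and 1097 only from liver, with 84.1% of IEL regions in spleen; recirculation genes kept 59.2% in salivary gland and effector genes 78.8% in liver (percentile 94.76). Cover of 50% gave shares in spleen of 80.8% (IEL), 91.1% (kidney), 87.8% (salivary gland), 89.9% (fat) and 88.8% (liver). At least 4 of 5 tissues gave 1566 resident-shared regions, and gene bodies with 50 kb gave 11.8% for recirculation genes in spleen alone. The cause was not tested for the windows, the cover and the gene bodies either. Recirculation genes in spleen alone stayed between percentiles 99.81 and 100 and residency genes in IEL alone between 95.87 and 99.65. The planned 50% rule changes nothing, as each interval lies in its own region, and the planned motif settings were not run. No paired analysis was possible because the lists carry no replicate numbers, so leaving out a library could not be done either. Unknown depth limits calls of weak regions in the shorter lists.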

Other observations

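The pair analyses were chosen after the lists were seen. IEL and salivary gland had 745 regions called in both and in no other list. Under independence, given each list's total of regions called in exactly 2 lists, 469.8 were expected. Those totals are fixed, so a pair above its expected number lowers other pairs. Residency genes held 23 of the 745, 4.20% of their 547 regions, at percentile 100 of matched lists. Such regions already count in the IEL and salivary gland gains over spleen given above, so the results are not independent. TGF-beta pathway genes held 10 (3.70%, percentile 99.475). Tspan9, Litaf and Ldlrad4 had 4 each; the genes of this part were chosen after their values were seen. Fat and liver had 350 such regions against 173.4, and no programme list stood apart. Lipid genes held 1 of these among their 109 regions (percentile 82.965). No gene had more than 2, and Tmem182, Ovol2 and Acly were among several genes with 2. Spleen and liver had 934 against 733.3, and recirculation genes stood apart with 17 (3.59%, percentile 99.62), as did macrophage and monocyte markers with 4 of 73 regions (percentile 98.73). Spleen and salivary gland had 317 against 545.4.

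T cell receptor loci differed between lists, although P14 cells carry a transgenic receptor. Of all 67286 union regions, 53888 were called in spleen, 43812 to 51640 in the tissues, and 7.37% in spleen alone, so part of the differences is general. At Tcra, the alpha chain locus, 145 of 168 regions were called in spleen, 27 of them in spleen alone, and 98 to 112 in the tissues. At Tcrb, 42 of 47 were called in spleen and 26 to 37 in the tissues. At Tcrg, the gamma chain locus beside Stard3nl, all 13 regions were called in IEL, 3 of them in IEL alone, and 9 or 10 in the other lists. Erg, an ETS factor gene of the endothelial list, had 4 of its 8 regions in IEL alone. Of the 13 gamma-delta T cell and innate lymphoid markers, 6 are on other lists. No explanation for these values was tested.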
